A study of Homo sapiens with 4 samples.

How the data were processed

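RNA sequencing libraries were compared from 2 human bladder cancer cell lines, EJ and T24T. Each line had been transfected either with the circular RNA hsa_circ_0008399 or with a vector control, which gave 4 groups of 1 library each. Extraction was from total RNA with TRIzol, per the labels' protocols. Trimmomatic, HISAT2 and the hg38 genome are named in the submitters' processing notes, without versions. The counting tool, the gene annotation, the use of strand and any pooling of replicates are not stated there.

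The authors deposited a table of read counts for 56303 genes and a table of RPKM values for the 29817 genes with 1 or more reads. In all 100% of its values the deposited RPKM equalled the count divided by gene length and by the library's total count, within a relative tolerance of 1e-06. Each column was matched to its sample by the sample's description, and 0 sample columns were left out. Columns and descriptions of 1 line read T24, while its titles and characteristics read T24T, the name used here. Both tables hold 1 value per gene, so the circular RNA itself has no value. Of the 56303 genes, 35452 matched the GENCODE release 29 annotation by symbol, chromosome, strand and overlap, and gene types and coordinates follow that build, hg38. Newer symbols in the gene lists were matched to the symbols in the table through synonyms and overlap.

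The deposited counts were the basis of all main results. Genes with 10 or more counts in at least 1 library and 20 or more over the 4 libraries were kept, 17689 in all. Counts were scaled by TMM, and log2 ratios of circ over vector were taken within each line with a prior count of 2. With 1 library per group, no p-value was computed within a line. Folds of single genes carry exact 95% binomial intervals, which cover counting error only. The sole replication of the transfection is its presence in both lines. It was tested with the edgeR quasi-likelihood test, with cell line as a block because libraries of the same line belong together, and with Benjamini-Hochberg adjustment at 0.05. This fit leaves 1 residual degree of freedom, so the spread of each gene rests mostly on information pooled over genes (30.5 prior degrees of freedom, common biological coefficient of variation 0.0704). The same fit compared the lines, with transfection as the block.

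Before the data were examined, 27 gene lists were fixed, covering TNF and NF-kB response, m6A machinery, exon junction complex and circRNA regulators, interferon and RNA sensing, apoptosis, platinum transport and detoxification, DNA repair, p53 targets, cell cycle, the integrated stress and unfolded protein response, heat shock, NRF2 targets, hypoxia and glycolysis, cholesterol biosynthesis, epithelial, mesenchymal, urothelial luminal and basal genes, immediate early genes, MAPK feedback genes, cytosolic ribosomal proteins, mitochondrially encoded proteins, the nuclear-encoded respiratory chain, histones, nuclear and small noncoding RNA, and leukocyte and endothelial or stromal markers. Lists with 3 or more tested members were compared with the other genes by limma camera, with a preset inter-gene correlation of 0.01 and with an estimated one. The estimated setting draws on the 1 residual degree of freedom of the fit, so hardly any list could pass it after adjustment. Where members of a list vary together more than the preset allows, the preset p-values are too small. Within each line, a list's median log2 ratio was placed among 10000 random lists matched on mean expression.

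Named genes follow a rule also fixed before the data were examined. It takes TNFAIP3, WTAP, METTL3, METTL14 and RBM3 always; up to 10 genes per direction that differ 2-fold the same way in both lines; up to 5 per direction with the largest ratio in each line; up to 5 per direction with the smallest adjusted p across lines; up to 3 members of each list with the largest mean ratio; and up to 5 per direction with the largest difference between the lines. The genes always taken, RBM3 among them, are ones that work on this circular RNA is known to concern. A minimum of 50 counts applied to the ratio-based parts, and clone or accession names were left out. The code first left out antisense and other valid symbols too, and this was corrected to the fixed rule after the results were seen. Other members of the fixed lists are cited as examples, and genes chosen after their values were seen are marked as such.

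The alternatives tried were RLE size factors, library size alone, no filter, a stricter filter of 50 counts in each line, prior counts of 0.5 and 10, RPKM on the log2(RPKM + 1) and log2(RPKM + 0.1) scales, a 1.5-fold threshold, DESeq2, limma-voom, limma on log2(RPKM + 1), no block, and each line alone. Removal of GC and length trends, thinning of all libraries to the smallest total, and exclusion of mitochondrial genes were added after seeing the data. A GC value was available for 98.9% of tested genes. The fit was checked on simulated counts with the real library sizes and the real common spread, for circ against vector across both lines over 17419 genes. It recovered 74 of 100 genes changed 1.5-fold and 99 of 100 changed 2-fold, with 13 calls among unchanged genes. With no gene changed it made 0 calls. The simulated genes shared 1 common spread and varied independently, with no culture effect on a whole library. The check, and the simulated counts of 2-fold genes given below, therefore do not cover those sources of difference.

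Analyses used R 4.3.3 with edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0; Python 3.11.15 with pandas 2.3.3 and matplotlib 3.10.9 prepared annotation and plots. Some counts are shared between genes. The gamma protocadherin genes, whose transcripts share constant exons, mostly carried nearly equal counts, PCDHGC3 excepted, so reads in overlapping exons appear to have been entered for more than 1 gene. HSPA1A and HSPA1B, histone and metallothionein genes, RN7SL1 and RN7SL2, and mitochondrial genes with nuclear copies have near-identical relatives, and their values are uncertain to that extent. The same holds for genes with an antisense neighbour, such as WTAP with SOD2 and RBM3 with RP11-1148L6.9.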

Results

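Gene expression was profiled by RNA sequencing in the human bladder cancer cell lines EJ and T24T, the latter written T24 in the deposited tables. In each line, 1 library came from cells transfected with the circular RNA hsa_circ_0008399 (circ) and 1 from cells transfected with the vector alone. Total counts were 15639289 in EJ vector, 14703455 in EJ circ, 16864247 in T24T vector and 18057768 in T24T circ. Genes with at least 1 read numbered between 23799 and 25044 per library. The first principal component, with 80.9% of the variance, parted the lines, and the second, with 13.02%, parted circ from vector in both lines. Within each line there is no replicate check on any difference.

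The series was designed to screen for genes downstream of the circular RNA, so circ was set against vector over both lines. RBM3, an RNA-binding protein gene on chromosome X (48574449 to 48579066, hg38), had the smallest adjusted p of all genes. It rose by a log2 fold change of 1.71 ± 0.10 (SE of the edgeR fit, n = 2 lines, edgeR adjusted p = 8.85e-14). Its counts went from 4361 to 16010 in EJ and from 4641 to 13240 in T24T. Each ± is such a standard error, which rests mostly on spread pooled over genes and does not measure agreement between the lines. The standard deviation of the log2 ratios of the 2 lines was 0.38 for RBM3, 0.09 for PPP1R15A and 1.56 for FOSB. The transfected circle itself has no value, as there is 1 value per gene, so its reads would be counted with the gene its exons come from. If those are exons of RBM3, the RBM3 rise may be construct reads in part or in whole. These values cannot tell such reads from the endogenous mRNA. TNFAIP3, which encodes the NF-kB inhibitor A20, rose by 1.29 ± 0.11 (edgeR adjusted p = 4.54e-10). The m6A writer genes WTAP (-0.01 ± 0.09, edgeR adjusted p = 0.962), METTL3 (-0.20 ± 0.11, 0.278) and METTL14 (0.11 ± 0.10, 0.529) did not pass the test. In all, 1262 genes rose and 984 fell among 17689 tested.

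After RBM3, the rises with the smallest adjusted p belonged to PPP1R15A, which encodes a phosphatase subunit acting on eIF2α (1.30 ± 0.08, edgeR adjusted p = 1.74e-12), the stress transcription factor gene ATF3 (1.98 ± 0.14, 2.92e-11), the embryonic myosin gene MYH3 (1.99 ± 0.16, 2.32e-10) and the zinc finger RNA-binding protein gene ZFR (1.03 ± 0.08, 4.54e-10). The corresponding falls belonged to INSIG1, a sterol-regulated ER protein gene (-1.14 ± 0.09, edgeR adjusted p = 8.39e-11), the mitochondrial 12S ribosomal RNA MT-RNR1 (-1.05 ± 0.09, 4.54e-10), the sterol reductase gene DHCR7 (-0.94 ± 0.09, 7.70e-09), the organic anion transporter gene SLCO4A1 (-0.93 ± 0.09, 1e-08) and HMG20B (-0.87 ± 0.09, 4.57e-08).

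**Figure D1:**
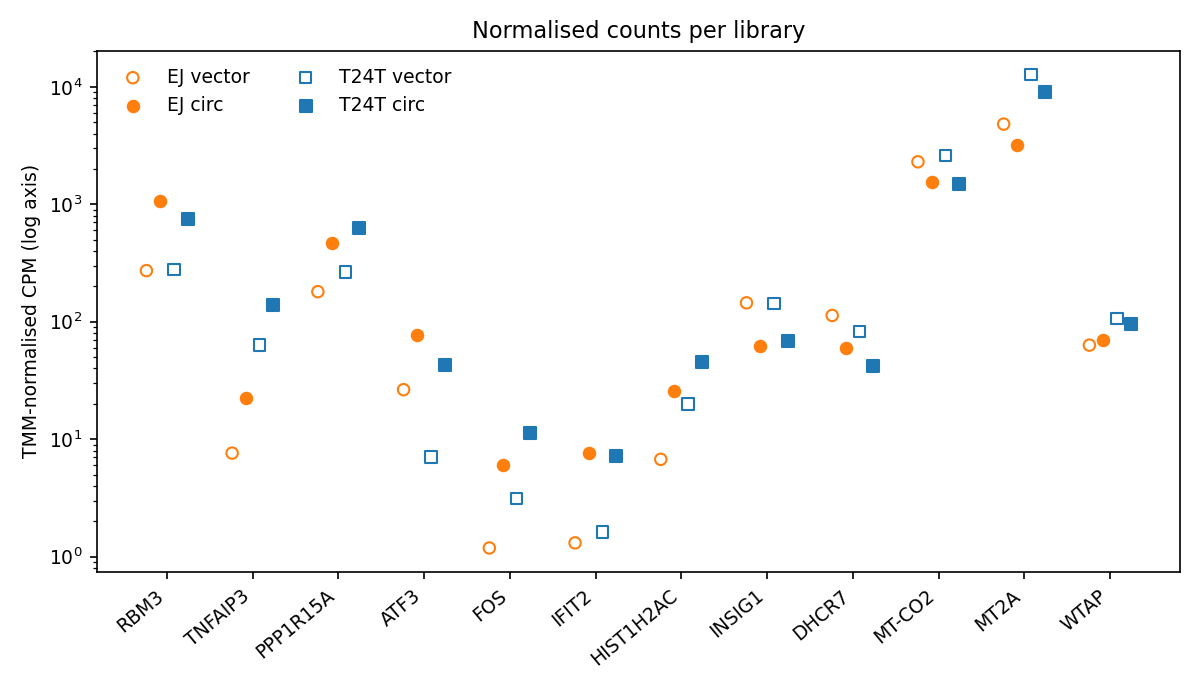
TMM-normalised CPM (log axis) of 12 genes in each of the 4 libraries, with open symbols for vector, filled symbols for circ, circles for EJ and squares for T24T. RBM3, TNFAIP3, PPP1R15A, ATF3, FOS, IFIT2 and HIST1H2AC lay higher in circ in both lines, INSIG1, DHCR7, MT-CO2 and MT2A lay lower, and WTAP went opposite ways.

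Genes of cholesterol biosynthesis fell together. Of 22 tested members, 20 fell and 1, PMVK, rose, with the same counts adjusted over the list alone (camera adjusted p = 8.47e-29; adjusted p = 0.636 with an estimated correlation). INSIG1 and DHCR7 led, and MSMO1 (-0.90 ± 0.13), LSS (-0.70 ± 0.08) and SQLE (-0.70 ± 0.09), which encodes squalene epoxidase, fell as well. The list's median log2 ratio was -0.55 in EJ and -0.54 in T24T, and all 10000 matched random lists lay above it in each line. DESeq2 also called 15 of these falls.

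Mitochondrially encoded mRNAs fell in the same comparison, all 13 of 13 (13 adjusted over the list alone; camera adjusted p = 1.22e-23; adjusted p = 0.636 with an estimated correlation). MT-CO2 fell by 0.70 ± 0.08, MT-ND5 by 0.67 ± 0.08 and MT-ND4 by 0.63 ± 0.08 on the log2 scale. The mitochondrial share of all counts was 5.40% in EJ vector and 4.01% in EJ circ, and 5.05% in T24T vector and 3.08% in T24T circ. Of 26 nuclear-encoded respiratory chain genes, 2 fell, NDUFC2 (-0.46 ± 0.13; -0.14 in EJ and -0.78 in T24T) and ATP5O (-0.30 ± 0.10), or 1 adjusted over the list alone (camera adjusted p = 0.171). Of 4 metallothionein genes, which bind metals including platinum, MT1X (-0.93 ± 0.15), MT1E (-0.74 ± 0.09) and MT2A (-0.55 ± 0.07) fell, and MT1F (0.16 ± 0.30, edgeR adjusted p = 0.791) did not pass. The former were the 3 members of 19 in the platinum transport and detoxification list that fell, MT1E and MT2A in DESeq2 as well, and none rose (1 rose and 3 fell adjusted over the list alone; camera adjusted p = 0.00490; adjusted p = 0.636 with an estimated correlation).

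Several stress genes moved the other way. In the integrated stress and unfolded protein response list, 11 of 25 members rose and 1 fell (15 and 2 adjusted over the list alone; camera adjusted p = 1.31e-14; adjusted p = 0.701 with an estimated correlation). DDIT3, encoding CHOP, rose by 1.23 ± 0.12, the ER chaperone gene HSPA5 by 0.85 ± 0.09 and the asparagine synthetase gene ASNS by 0.85 ± 0.16. The fall was that of CHAC1 (-1.504 ± 0.40) and rests on EJ, since T24T had 7 and 6 counts. DESeq2 called 4 of the rises, those of ATF3, DDIT3, HSPA5 and PPP1R15A. The list's median was 0.12 in EJ, at the 97.1 percentile of matched lists, and 0.59 in T24T, above all of them. ASNS shows the gap between the lines, with a log2 ratio of 0.13 in EJ and 1.58 in T24T. Of 15 heat shock genes, 6 rose and 2 fell (8 and 3 adjusted over the list alone; camera adjusted p = 0.00110; adjusted p = 0.636 with an estimated correlation). HSPA1A (1.13 ± 0.11), HSPA1B (1.13 ± 0.12) and BAG3 (0.57 ± 0.10) were among the rises, and HSPD1 (-0.27) and HSPB1 (-0.26) fell. DESeq2 called BAG3 alone. The heat shock list's median was 0.13 in EJ, at the 94.1 percentile of matched lists, and 0.14 in T24T, at the 81.7 percentile. Both lay within the matched range.

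Of 18 immediate early genes, 9 rose and none fell (11 adjusted over the list alone; camera adjusted p = 1.51e-12; adjusted p = 0.636 with an estimated correlation). FOSB rose by 2.45 ± 0.26, FOS by 2.02 ± 0.21, ATF3 by 1.98 ± 0.14 and JUN by 0.78 ± 0.09, of which DESeq2 called the last 2 and no other member. EGR1 passed the test (1.03 ± 0.24, edgeR adjusted p = 0.00330) with a log2 ratio of -0.03 in EJ and 2.36 in T24T, so its rise rests on T24T. Interferon-induced genes rose in 6 of 20 cases and fell in none (8 adjusted over the list alone; camera adjusted p = 4.68e-06; adjusted p = 0.636 with an estimated correlation). IFIT2 rose by 2.32 ± 0.24, IFIT3 by 1.10 ± 0.20 and ISG15 by 0.74 ± 0.14, from vector counts between 21 and 230, and IFIT1 rose as well. DESeq2 called 0 of these 6 rises. The median of that list was 0.39 in EJ, above all matched lists, and 0.24 in T24T, at the 99.3 percentile.

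In the list of exon junction complex and circRNA regulators, 9 of 17 members rose and none fell (10 adjusted over the list alone; camera adjusted p = 3.84e-09; adjusted p = 0.636 with an estimated correlation). Besides RBM3 these were, among others, the nonsense-mediated decay genes UPF3B (0.69 ± 0.08) and UPF2 (0.69 ± 0.09), the exon junction core gene MAGOHB (0.68 ± 0.09) and the cold-inducible CIRBP (0.53 ± 0.10). DESeq2 called RBM3, UPF3B, UPF2 and MAGOHB. EIF4A3 rose by 0.29. In the m6A list, YTHDC1 (0.30 ± 0.09) and KIAA1429 (0.27 ± 0.09) rose among 21 members, and RBM15 (0.35 ± 0.12, edgeR adjusted p = 0.0584) did not pass (4 rose adjusted over the list alone; camera adjusted p = 0.748). That list's median of -0.01 and mean of 0.03 differ in sign.

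Histone mRNAs, which mostly lack poly(A) tails and so also mirror how RNA was selected, rose in 9 of 14 cases and fell in none (12 adjusted over the list alone; camera adjusted p = 4.81e-12; adjusted p = 0.636 with an estimated correlation). HIST1H2AC, the 1 member that DESeq2 called, rose by 1.49 ± 0.13 and HIST1H2BD by 1.52 ± 0.21, and the list's median was 1.38 in EJ and 0.77 in T24T. Of 23 listed histone genes, 14 could be tested and 4 had 50 counts in each line, so the rise speaks for part of the list. Of 10 nuclear and small noncoding RNAs, GAS5 rose (0.27) and 4 fell (2 and 4 adjusted over the list alone; camera adjusted p = 0.183, and 0.0282 with RLE scaling). RN7SK (-1.40 ± 0.16), RN7SL1 (-1.22 ± 0.22), RN7SL2 (-0.97 ± 0.19) and RMRP (-1.66 ± 0.54) fell mostly in T24T. In EJ the log2 ratios were -0.49 for RN7SK, 0.20 for RN7SL1, 0.05 for RN7SL2 and 0.07 for RMRP. The mean of this list was -0.41 and its median 0.08. Its median log2 ratio was 0.24 in EJ, at the 98.4 percentile of matched lists, and -0.20 in T24T, at the 2.79 percentile. The small noncoding RNAs thus had no shift shared by the lines. The histone rise appeared with circ in both lines, in the same libraries as the mitochondrial, cholesterol and stress gene changes. Whether it came from RNA selection was not tested.

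Hypoxia and glycolysis genes rose in 8 of 22 cases and fell in none (9 and 1 adjusted over the list alone; camera adjusted p = 0.000380; adjusted p = 0.850 with an estimated correlation). The vasodilator peptide gene ADM rose by 2.36 ± 0.24 and the hexokinase gene HK2, the 1 member that DESeq2 called, by 0.85 ± 0.12. ANKRD37 (0.79 ± 0.22) went from 109 to 95 counts in EJ and from 88 to 267 in T24T. The list's median was -0.10 in EJ and 0.37 in T24T, and this difference between lines was not tested. In the TNF and NF-kB list, 5 of 25 rose and 2 fell (6 and 4 adjusted over the list alone; camera adjusted p = 0.0853). TRAF1 (0.74 ± 0.17) and NFKBIB (0.53 ± 0.11) rose beside TNFAIP3, while the cytokine genes CCL20 (-0.96 ± 0.17) and IL1B (-1.07 ± 0.35) fell, which rests on T24T, as the EJ libraries had 6 and 4 counts of CCL20 and 2 and 0 of IL1B. Mesenchymal and matrix genes fell in 2 of 16 cases and rose in 1 (1 rose and 3 fell adjusted over the list alone; camera adjusted p = 0.0302; adjusted p = 0.637 with an estimated correlation). FN1, encoding fibronectin, fell by 0.73 ± 0.09 and the tenascin gene TNC by 0.39 ± 0.08, while ZEB2 rose (0.77); DESeq2 called FN1 and TNC.

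The remaining lists were not called, and of their passing members DESeq2 called CCNG1, KRT7 and CLDN1. Cell cycle genes were split, with 4 rises and 5 falls among 26 (5 and 7 adjusted over the list alone; camera adjusted p = 0.439): the replication genes MCM6 (0.33 ± 0.09) and CCNE2 (0.45 ± 0.12) rose, and the mitotic genes FOXM1 (-0.38 ± 0.09) and TOP2A (-0.30 ± 0.08) fell. NRF2 targets gave 3 rises, including OSGIN1 (0.62 ± 0.20) and HMOX1 (0.48 ± 0.15), and 5 falls among 20 (4 and 6 adjusted over the list alone, camera adjusted p = 0.439). HMOX1 had log2 ratios of 1.20 in EJ and 0.05 in T24T. The NRF2 list's median was -0.23 in EJ and -0.16 in T24T, at percentiles of 0.040 and 0.60 of matched lists. In both lines 12 members were lower and 4 higher. Of 19 p53 targets, GADD45A (0.54 ± 0.11; 0.17 in EJ and 0.86 in T24T) and AEN (0.44 ± 0.11) rose, and CCNG1 (-0.73 ± 0.10) and FDXR (-0.31) fell (4 and 2 adjusted over the list alone; camera adjusted p = 0.735, upward as the mean of 0.06, against a median of -0.02). Apoptosis regulators gave 3 rises, PMAIP1 (0.48 ± 0.10), BCL2L2 (0.37 ± 0.10) and CASP8 (0.34 ± 0.10), and 2 falls, BCL2L1 (-0.34) and BIRC5 (-0.27), among 24 (3 and 2 adjusted over the list alone; camera adjusted p = 0.760, upward against a mean of -0.0046).

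DNA repair genes gave rises of XPA (0.34 ± 0.11) and MSH6 (0.31 ± 0.08) and the fall of TOP2A among 27 (2 and 1 adjusted over the list alone; camera adjusted p = 0.439). Of 12 epithelial genes, KRT7 (0.37 ± 0.08), DSP (0.29) and LAMB3 (0.24) rose, and CLDN1 (-0.58 ± 0.09) and JUP (-0.38 ± 0.09) fell (3 and 2 adjusted over the list alone; camera adjusted p = 0.748). Of 16 MAPK feedback genes, FOSL1 rose (0.38 ± 0.09) and ETV4 fell (-0.36 ± 0.10) (1 and 2 adjusted over the list alone; camera adjusted p = 0.439). SPRY4 had -0.28 ± 0.10 and did not pass. Of 29 cytosolic ribosomal protein genes, RPL27 (0.30 ± 0.08) and RPL5 (0.23 ± 0.08) rose (1 adjusted over the list alone; camera adjusted p = 0.538), and RPL30 had -0.24 ± 0.08 without passing. No urothelial luminal gene passed among 11 (0 adjusted over the list alone; camera adjusted p = 0.222), with ERBB3 at -0.34 ± 0.13, TRIM24 at -0.23 ± 0.11 and ERBB2 at -0.22 ± 0.09. Of the 3 endothelial or stromal markers tested, RGS5 rose (0.72 ± 0.22) and MYH11 fell (-0.75 ± 0.21), each 1 adjusted over the list alone (camera adjusted p = 0.931). Among leukocyte markers CD68 alone was testable (0.29 ± 0.11, edgeR adjusted p = 0.0905), and among urothelial basal markers CD44 (-0.10 ± 0.09, 0.514) and EGFR (-0.20 ± 0.08, 0.122).

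**Figure D2:**
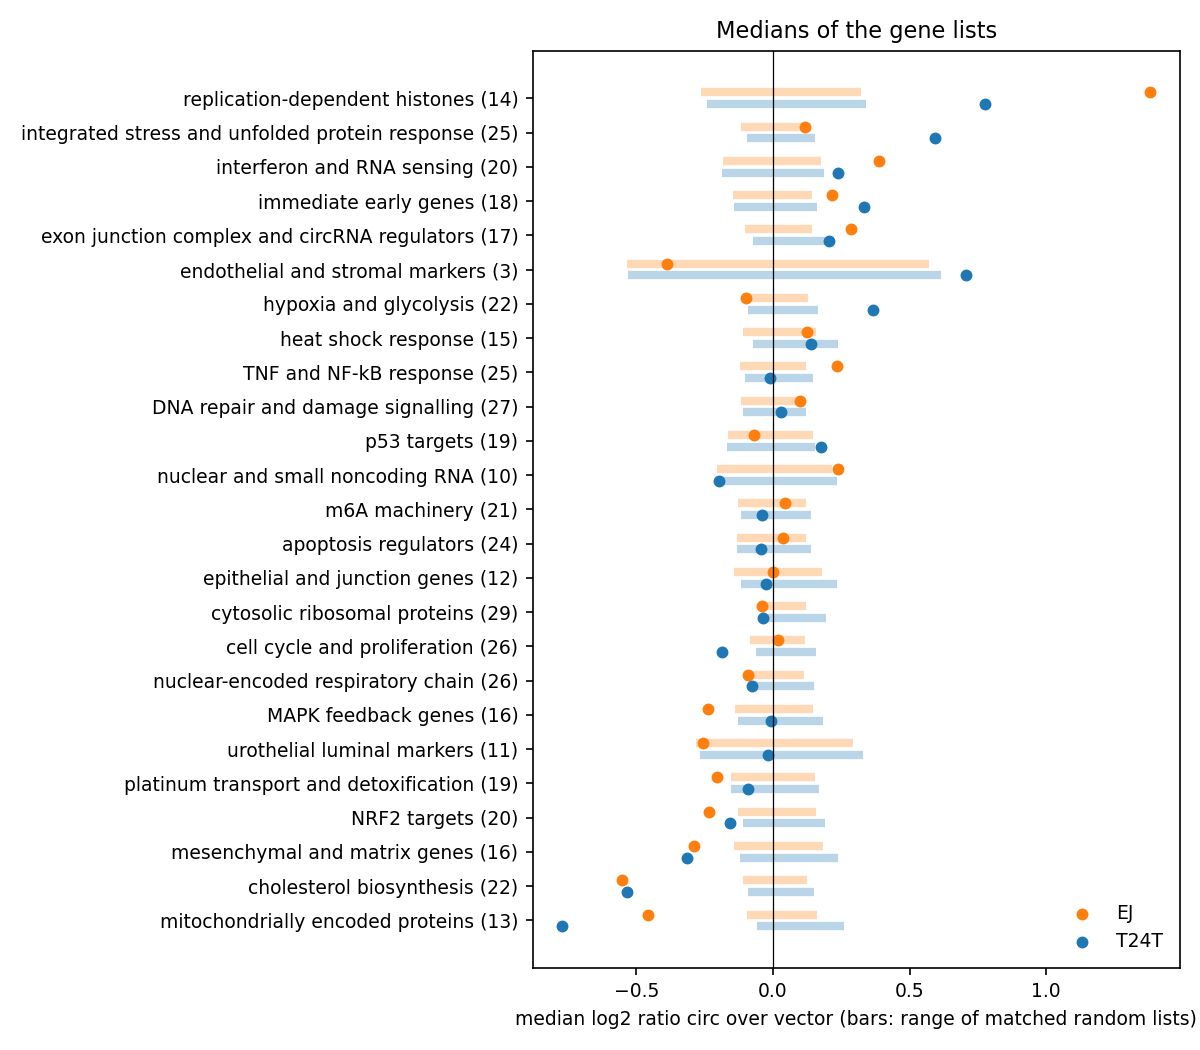
Median log2 ratio of circ over vector in EJ (orange) and T24T (blue) for each gene list, with the number of tested members in brackets and, as bars, the 95% range of 10000 random lists matched on mean expression. Cholesterol biosynthesis (-0.55 and -0.54), mitochondrially encoded, NRF2 target and mesenchymal genes lay below the range in both lines, and the nuclear-encoded respiratory chain lay just below it. Histone, interferon, immediate early and exon junction genes lay above it in both lines.

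The size of this comparison depends on the model. DESeq2 called 341 of the 2246 genes, RBM3, TNFAIP3, ATF3, INSIG1 and all 13 mitochondrial mRNAs among them; without the cell-line block edgeR called 0 genes (397 at an unadjusted p under 0.05), and limma on log2(RPKM + 1) called 0 (3588 unadjusted).

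In EJ alone, 400 genes were at least 2-fold higher in circ and 277 at least 2-fold lower, 3.83% of tested genes. FOSB was 16.2-fold higher (95% counting interval 9.26 to 31.0), HIST1H2BG 9.74-fold (4.89 to 22.1), the cardiac ankyrin repeat gene ANKRD1 7.02-fold (5.59 to 8.90), NFATC2 6.15-fold (3.80 to 10.4) and IFIT2 5.81-fold (3.62 to 9.74). RBM3 was 3.93-fold higher (3.80 to 4.06) and TNFAIP3 2.97-fold (2.41 to 3.69). SDCBP2 was 4.67-fold lower (2.71 to 8.57), CHAC1 3.53-fold (2.08 to 6.31), EVA1B 3.46-fold (2.16 to 5.74), the antisense transcript SNAI3-AS1 2.67-fold (1.60 to 4.62) and the collagen gene COL6A2 2.66-fold (1.55 to 4.75). The TNF and NF-kB list had a median log2 ratio of 0.23, above nearly all matched lists, against -0.01 in T24T, and the MAPK feedback list one of -0.24, at a percentile of 0.040, against -0.0058 in T24T. Low counts weigh on these numbers: of the 12743 genes with 50 counts in the higher EJ library, 54 were 2-fold higher and 35 lower, and libraries simulated with no changed gene gave 306 genes with a 2-fold difference in EJ.

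In T24T, 446 genes were at least 2-fold higher in circ and 246 at least 2-fold lower, 3.91% of tested genes. ADM was 6.62-fold higher (4.76 to 9.42), AMH, encoding anti-Müllerian hormone, 6.29-fold (3.70 to 11.4), ATF3 6.14-fold (5.05 to 7.53), the glycogen-targeting gene PPP1R3C 6.11-fold (3.59 to 11.1) and EGR1 5.18-fold (4.45 to 6.06). RBM3 was 2.71-fold higher (2.62 to 2.80) and TNFAIP3 2.20-fold (2.05 to 2.37). The urea transporter gene SLC14A1 was 4.55-fold lower (3.18 to 6.65), the signal recognition particle RNA RN7SL1 3.58-fold (3.08 to 4.17), the pseudogene HNRNPA1P54 3.62-fold (2.05 to 6.77), the small nuclear RNA RN7SK 3.25-fold (2.85 to 3.72) and SDCBP2 3.20-fold (2.03 to 5.20). PPP1R3C had 35 and 27 counts in EJ vector and circ, a log2 ratio of -0.26. The cell cycle list had a median of -0.19 in T24T, at a percentile of 0.010, against 0.02 in EJ. Of the 13327 genes with 50 counts in the higher T24T library, 105 were 2-fold higher and 54 lower, and libraries simulated with no changed gene gave 196 genes with a 2-fold difference in T24T.

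Genes that differed 2-fold the same way in both lines numbered 103 higher and 31 lower, where independent lists would share 10.1 and 3.85. Libraries simulated with no changed gene gave 5 higher and 4 lower in both lines. In opposite directions, 7 genes were higher in EJ and lower in T24T (5.56 expected), and 14 were lower in EJ and higher in T24T (6.98 expected). Among the 12463 genes with 50 counts in each line, 19 were higher in both and 3 lower, against 0.255 and 0.0672 expected. Ranked by the smaller of the ratios, the first were HIST1H2BG (log2 ratios 3.03 and 2.20 in EJ and T24T), IFIT2 (2.43 and 2.06), MYH3 (2.14 and 1.84), AMH (1.83 and 2.51), FOS (2.23 and 1.82), FOSB (3.83 and 1.63), ATF3 (1.54 and 2.60), ADM (1.44 and 2.67), HIST1H2BD (1.54 and 1.44) and RBM3 (1.97 and 1.44). On the lower side stood SDCBP2 (-2.10 and -1.60), the noncoding SNAI3-AS1 (-1.34 and -1.21) and INSIG1 (-1.21 and -1.06). Over these 12463 genes the ratios of the lines correlated with Pearson's r of 0.569 and Spearman's rho of 0.548, and 69.6% had the same sign. These correlations are across genes, which are not independent replicates. Over all tested genes r was 0.363.

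**Figure D3:**
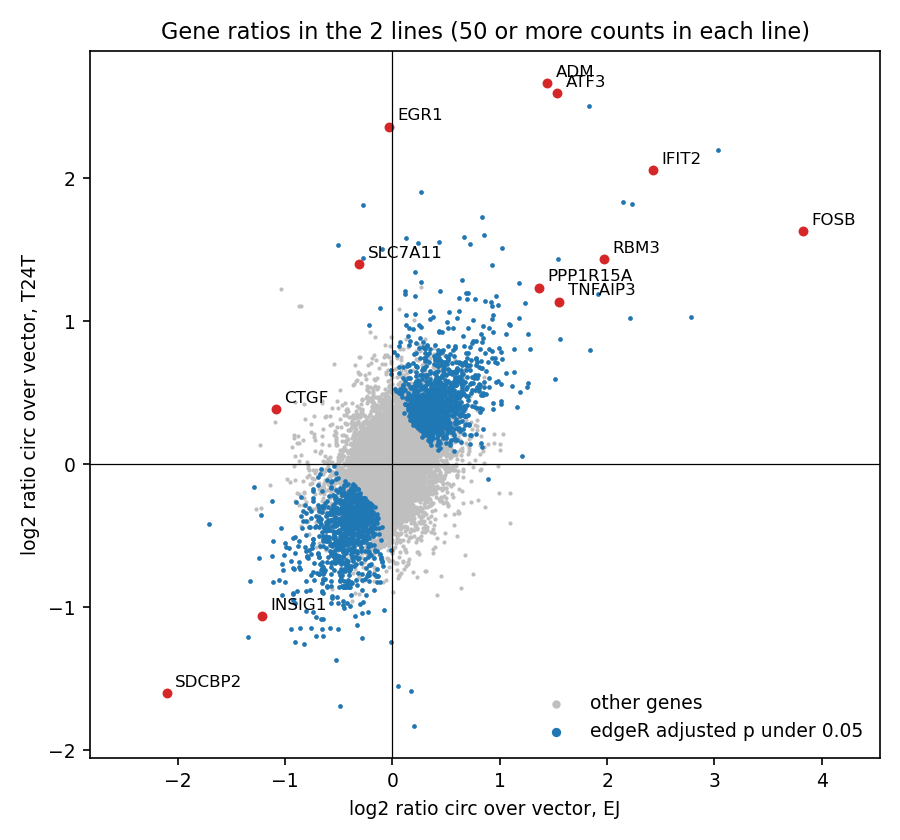
Log2 ratio of circ over vector in EJ (horizontal) against T24T (vertical) for the 12463 genes with 50 counts in each line, with genes of edgeR adjusted p under 0.05 in blue, other genes in grey and genes given by name in red. RBM3 lies at 1.97 and 1.44 and INSIG1 at -1.21 and -1.06, while EGR1, SLC7A11 and CTGF lie off the diagonal.

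The lines themselves differed far more than circ from vector. Per the edgeR fit, 3870 genes were higher in T24T and 3445 in EJ. With 0 counts in both EJ libraries, the lipolysis inhibitor gene G0S2 was at least 792-fold higher in T24T, measured against a floor of 3 counts over the EJ libraries. On the same basis LCN2, encoding lipocalin 2, was at least 92.4-fold, the lectin gene CLEC4E at least 90.5-fold and ATXN1 at least 88.4-fold higher. Exact 95% counting intervals, which are wider, begin at 644 for G0S2, 74.7 for LCN2, 73.2 for CLEC4E and 71.5 for ATXN1. The growth factor gene CSF3 had 1 count in EJ and 5395 in T24T, a ratio of 4901 (95% counting interval 879 to 193625). In the other direction, the guanine exchange factor gene VAV3 was 399-fold higher in EJ (223 to 801), the syndecan gene SDC2 223-fold (102 to 609), ALPK2 134-fold (82.6 to 236), the teneurin gene TENM2 129-fold (78.0 to 231) and NEBL 122-fold (47.4 to 450).

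T24T carried more inflammatory and hypoxia transcripts. Of 25 TNF and NF-kB genes, 23 were higher in T24T and 1 in EJ, with IL6 (log2 fold change 6.66), CXCL1 (5.67), CXCL8 (5.19) and TNFAIP3 (2.80 ± 0.11) among the former. Of 22 hypoxia and glycolysis genes, 20 were higher in T24T and 1 in EJ, including NDRG1 (2.64), VEGFA (2.12) and LDHA (1.46). Cytosolic ribosomal protein genes were higher in T24T in 23 of 29 cases and in EJ in none, for example RPL15 (0.82) and RPL11 (0.80). Metallothionein gene MT2A (1.45 ± 0.07) and fibronectin gene FN1 (2.71 ± 0.09) were higher in T24T as well. Epithelial and mesenchymal genes were mixed. Of 12 epithelial genes, 7 were higher in T24T, such as EPCAM (4.21) and KRT8 (2.51), and 5 in EJ, such as JUP (-0.57) and KRT7 (-0.28). Of 16 mesenchymal and matrix genes, 8 were higher in T24T, TNC (0.63) and FN1 among them, and 3 in EJ, including the N-cadherin gene CDH2 (-3.51). DESeq2 called 3203 of these 7315 genes, and edgeR without the transfection block called 3192. No camera test was run on this comparison.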

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

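Tests chosen only after the result was seen were those of construct reads at RBM3, of the nuclear share of RNA, of the nuclear-encoded respiratory chain, of GC content and length, of thinned depth and of scaling without mitochondrial genes. Among the genes named, 3 had log2 ratios of opposite sign in the lines, each beyond its counting interval, and these differences between lines were not tested. CTGF, a matrix-associated growth factor gene, was lower in circ in EJ (-1.08) and higher in T24T (0.38), a difference of 1.47. SLC7A11, the cystine transporter gene, had -0.31 in EJ and 1.40 in T24T, a difference of 1.71. WTAP had 0.16 in EJ and -0.16 in T24T, a difference of -0.32.

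Most genes called between circ and vector across the lines stayed called in the technical checks made. After each library's trend on GC content and gene length was removed, 89.5% of the 2246 called genes were still called. After all libraries were thinned to the smallest total, 95.3% were. A culture or plate difference that goes with the transfection cannot be told apart from an effect of the circular RNA, since there was 1 vector library per cell line. The circular RNA remains among the open explanations, untested beyond this.

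The RBM3 rise was not shared by its chromosomal surroundings: the 23 tested genes within 500 kb had a median log2 fold change of -0.18. A cold-type response may contribute, but CIRBP, the other classic cold-inducible gene, rose by 0.53, which lies between the bounds set for and against it. Reads from the transfected construct cannot be told apart from the endogenous mRNA if the circle carries RBM3 exons, as the gene's 1.71 is a value over the whole gene and exon-level values were not used here. An effect of the circle on the RBM3 gene stays open.

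The lower mitochondrially encoded RNA did not come from the scaling, since the 13 mRNAs kept a median log2 ratio of -0.62 when library sizes and scaling were taken from other genes. A fall of like size in all respiratory chain transcripts is argued against by the nuclear-encoded members. Their median log2 fold change was -0.0849, against -0.60 for the mitochondrial list. A smaller fall of the nuclear-encoded members is not excluded. Their median log2 ratio was -0.0918 in EJ and -0.0755 in T24T, at the 2.46 and 1.54 percentiles of matched lists. A larger nuclear share of the RNA cannot be told apart from a mitochondrial change, because the 2 testable nuclear-retained transcripts, MALAT1 and NEAT1, had a median of 0.17, between the bounds set, and KCNQ1OT1 had too few counts. A biological effect of the transfection on mitochondrial RNA stays open as well.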

How the results depend on the processing

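The corrections for GC content and length, the thinning and the exclusion of mitochondrial genes were chosen after seeing the data. Unless a value shows it, the cause of a change was not tested. The counts of 2-fold genes in EJ (677), T24T (692) and both lines (134) rest on low counts. With no filter they were 2314, 1679 and 263, with the stricter filter 71, 100 and 22, with a prior count of 10 they were 125, 182 and 28, on log2(RPKM + 1) 75, 114 and 17, and at a 1.5-fold threshold 2352, 2449 and 688; the filters and the threshold change which genes can count. A prior count of 0.5 gave 963, 894 and 192, and RLE size factors 668, 694 and 131. Without a filter, the higher share among 2-fold genes in both lines went from 76.9% to 65.4%, and with the stricter filter to 86.4%, a prior count of 10 to 89.3% and log2(RPKM + 1) to 94.1%.

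Of the 2246 genes called across lines, DESeq2 called 341. It left 1063 uncalled and gave 842 no adjusted p, because its own filter set 11317 genes aside. Of the 85 named genes that edgeR called, DESeq2 called 26, left 24 uncalled and gave 35 no adjusted p. Without the cell-line block 0 genes were called, as the difference between lines then counts as spread, and limma on log2(RPKM + 1) called 0. RLE (2659), limma-voom (2348), no filter (2248), the stricter filter (1724), the GC and length correction (2146), thinning (2399) and exclusion of mitochondrial genes (2138) differed less. RLE moved the split from 1262 higher and 984 lower to 1380 and 1279. Between lines, the 7315 calls became 3203 with DESeq2 and 3192 without the block. Of the 11 lists called by camera, 0 were called with an estimated correlation (smallest unadjusted p 0.0645). That setting draws on 1 residual degree of freedom, so this outcome was close to fixed in advance. The immediate early list's estimated correlation of -0.0065 lay below the preset 0.01, yet its unadjusted camera p went from 2.41e-13 to 0.0799. The loss of calls therefore weighs neither for nor against the lists. The estimated correlation was 0.042 for interferon, 0.030 for cholesterol, -0.029 for platinum, -0.05 for mesenchymal and -0.067 for heat shock genes. It lay far above the preset for the mitochondrial (1), hypoxia (0.818), integrated stress (0.693), histone (0.121) and exon junction (0.118) lists. Such estimates are rough, but if members vary together to that extent, the camera p-values at the preset are far too small. Without the block 8 lists were called, losing platinum (0.0698), hypoxia (0.0614) and mesenchymal genes (0.0623). RLE added the small noncoding RNA list (0.0282).

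List medians that changed sign were those of the mesenchymal list in T24T (0.19 with the stricter filter) and of the endothelial and stromal list in T24T (-0.0288 with no filter, -0.0988 with the stricter filter), where the filters change the members. Of the 82 named genes that edgeR called and that were also read in each line alone, 5 had opposite signs in EJ and T24T: PPP1R3C (-0.26 and 2.47), EGR1 (-0.0292 and 2.36), ANKRD37 (-0.0994 in EJ), RN7SL1 (0.20 and -1.83) and RN7SL2 (0.0532 and -1.55). Uncalled genes can differ in sign too, such as VAV3 (-0.39 with edgeR, 0.55 with DESeq2).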

Other observations

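The groups in this part, and the test on nonsense-mediated decay, were chosen after the data were seen, so their counts describe these libraries and test nothing. Ribosome biogenesis factors were higher with circ: edgeR called 21 of 32 up and none down, with medians of 0.39 in EJ and 0.31 in T24T. Among them were UTP14A (0.73), PES1 (0.69), RRP12 (0.65), GTPBP4 (0.62) and NOP2 (0.62), and DESeq2 called 11 of the 21. Of 29 spliceosome and SR protein genes, 13 were called up, led by PNN (0.67), CLK4 (0.50) and SRSF7 (0.47), and 1, SRSF2 (-0.27), down, and DESeq2 called 5 of the 13. Genes of a list of fatty acid synthesis and SREBP1 targets were lower beside the cholesterol genes. Of 16, 13 were called down and none up, including TMEM97 (-1.04), ACSS2 (-0.78), FASN (-0.75), SCD (-0.72) and SREBF1 (-0.45), while GPAM (0.38), FADS1 (0.06) and FADS2 (0.02) were not called, and DESeq2 called 8 of the 13.

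Of 22 mitochondrial tRNAs, 21 were called down, 9 of them by DESeq2 as well, and MT-TV (0.21) was not called. Reads that reach into a neighbouring mitochondrial gene may have been entered for both. The tRNA falls may therefore not be separate from those of the mitochondrial mRNAs and ribosomal RNA. All 22 gamma protocadherin genes were called down, but they share constant exons and most carried nearly equal counts, such as 1364 in T24T vector for both PCDHGA1 and PCDHGA7, so most are close to 1 measurement. PCDHGC3, with 3214 counts there, stood apart. RP11-1148L6.9, which overlaps RBM3 on the opposite strand, rose by 0.60, and reads of the pair cannot be separated without knowing the use of strand.

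Nonsense-mediated decay factors were higher with circ, with 7 of 14 called up, among them UPF3B (0.69), UPF2 (0.69), SMG5 (0.52) and SMG1 (0.43), the 4 that DESeq2 called as well, and none down. Since these factors' own transcripts rise when the pathway is less active, one hypothesis is that decay was lower with circ, which would raise the snoRNA host transcripts that it degrades. Their median of the mean log2 ratio was 0.24, between the bounds set for and against lower decay. Of the 11 hosts, 4 were called up, EPB41L4A-AS1 (0.61), SNHG8 (0.59), ZFAS1 (0.56) and GAS5 (0.27), and 1, SNHG16 (-0.38), down, DESeq2 called ZFAS1 alone, and the hypothesis stays open.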
